A study of Saccharomyces cerevisiae
Nakaseomyces glabratus with 8 samples.

How the data were processed

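Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Top2, the yeast type II topoisomerase, in Saccharomyces cerevisiae cells of the SK1 background going through synchronous meiosis. Per the labels, cells carried myc-tagged Top2 or no tag and were put into potassium acetate sporulation medium. Samples of the tagged strain were taken at 0, 2 and 4 h, and of the untagged strain at 4 h. Crosslinking took 15 min with formaldehyde at 1%, and the cells were mixed with crosslinked Candida glabrata cells of strain CBS138, at 10 S. cerevisiae cells per C. glabrata cell. The C. glabrata chromatin serves as a spike-in, an outside reference of constant amount. The mixture was sonicated, and an anti-myc antibody was used for the immunoprecipitation (IP). Each of the 4 IP libraries has a whole cell extract (WCE) library, the input before the IP, so that there are 8 samples with 1 library per group.

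The authors deposited read counts for each library, which are whole numbers of reads in total, after clipping, aligned to the S. cerevisiae assembly ASM205788v1 and aligned to C. glabrata, per the file headers. Deposited beside the counts are the authors' calibration values, each a ratio: the occupancy ratio, a scaling to a fixed number of aligned reads, and their product. Recomputing these from the counts gave the same values to rounding, with the occupancy ratio equal to the S. cerevisiae reads per C. glabrata read of the IP divided by the same quotient of the WCE. For each IP library the authors also deposited a signal track, the whole-number fragment depth at each position of ASM205788v1 with positions at 0 left out, per the file headers and the values. The signal was not scaled by library size or calibration. Trimming with cutadapt and the use of Picard 1.119 are named in the submitters' processing notes. The aligner, its filters and its handling of reads that match several places are not given in the sources used here, so signal in repeated sequence is uncertain. Tracks of the WCE libraries were not used here.

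The depth of the IP libraries was 10571808 reads in total at 0 h, 6187114 at 2 h, 10921525 at 4 h and 3154564 for the untagged strain. Summed depth divided by aligned reads gave mean fragments of 220, 188, 214 and 187 bp in that order. Intervals of 95% were computed from read counts on the log scale for occupancy ratios and as exact binomial intervals for regions. They cover counting error only, and with 1 library per group they hold no variation between cultures. No test across samples was made, and no p-value was computed across bins or regions.

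Depth was averaged in 100 bp bins over the 16 nuclear chromosomes. Sequence 17, by its number and its length of 84637 bp taken to be mitochondrial DNA, was left out of all values from the tracks. Its reads are part of the occupancy ratios, which use all reads aligned to S. cerevisiae. Of 120604 bins, 119689 had depth in at least 1 track and were used. Relative signal is a bin's depth over the median bin of its own track, and calibrated depth is the depth times the authors' deposited factor. The factor is made from reads, so calibrated depth scales with a library's mean fragment length. Folds per fragment, added after seeing the data, divide it by that length. A bin was called enriched when its relative signal was at least 2 and the tagged over untagged quotient, with a pseudocount of 0.1, was also at least 2. Enriched bins with at most 1 bin between them were joined, and regions under 200 bp were dropped. Changes over time were measured over the union of the regions of the 3 times. Overlap of regions was set against independent placement and against 1000 circular shifts along each chromosome. Pearson and Spearman correlations between tracks used 1 kb bins, with bins not taken as replicates. The correlation of mean relative signal with chromosome length over 16 chromosomes has a two-sided permutation p from 100000 permutations, adjusted by the Benjamini-Hochberg method over 4 libraries, as a description of each library.

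The rule for naming regions was fixed in advance. It takes the 10 regions at 4 h with the highest tagged over untagged quotient, and the 5 with the largest rise and the 5 with the largest fall of relative signal that move one way over all 3 times. Regions within 20 kb of a chromosome end, or with untagged relative signal over 3, are left out, and the 3 bins with the highest untagged relative signal are named as background. Regions are given by position because no annotation of ASM205788v1 was used here. For that reason the planned signal by gene part, the promoter signal of gene lists and the values of named genes could not be run. The gene table at hand belongs to another assembly, and no coordinates were moved between assemblies.

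Settings tried beside the main ones, fixed before the data were examined, changed the calibration, bin width, thresholds, pseudocount, handling of chromosome ends and bins with extreme untagged signal, and the set of regions. Others, listed in the closing section, were chosen after seeing the data. The region caller was tested on simulated fragments drawn at the depth of each tagged library from the smoothed untagged profile, with planted regions of 500 bp. At the 0 h depth it found 44 of 46 planted regions of 3-fold and 10 of 47 of 2-fold, and at the 4 h depth 46 of 47 and 14 of 49. It called 0 regions in simulations with no planted change. Both simulated tracks came from the same smoothed profile, so this does not give the rate of false calls in the real tracks. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.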

Results

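Top2 relieves supercoiling and unlinks DNA by cutting the duplex and passing another through the break. Its binding to the genome was measured in meiotic yeast cells at 0, 2 and 4 h in sporulation medium by spike-in calibrated ChIP-seq, with an untagged strain at 4 h as the background. Each group was 1 IP library with its WCE library, so none of the differences given here has a replicate check. The IP libraries held 6931293 S. cerevisiae reads at 0 h, 3903703 at 2 h, 8782703 at 4 h and 1647198 in the untagged strain. The WCE libraries were shallower, from 791763 to 1520103 reads in total.

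The first comparison asks how much chromatin the antibody recovered because of the tag. At 4 h the tagged strain gave 17.6 S. cerevisiae reads per C. glabrata read in the IP, and the untagged strain 1.61. Corrected for the WCE, the occupancy ratio was 1.83 (95% counting interval 1.81 to 1.84) with the tag and 0.189 (0.188 to 0.190) without it. The tagged strain thus recovered 9.66 times as much (9.57 to 9.74). Across the chromosomes the median bin had a calibrated depth of 233 in the tagged and 26.3 in the untagged library, an 8.87-fold difference, or 7.72-fold per fragment, since depth also scales with the mean fragment length of a library. The 0 h library, with an occupancy ratio of 0.761 (0.756 to 0.767), lay 4.03-fold above the untagged one, which was taken at another time.

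The second comparison follows Top2 occupancy through early meiosis, relative to the S. cerevisiae chromatin in the WCE. In the WCE there were 7.18 S. cerevisiae reads per C. glabrata read at 0 h, 7.62 at 2 h and 9.64 at 4 h. The ratio divides by this quotient, and without it 4 h was 3.22-fold above 0 h in the IP. Occupancy was 0.761 at 0 h, 0.938 (0.932 to 0.945) at 2 h and 1.83 at 4 h. The 2 h library was 1.23-fold above 0 h (1.22 to 1.25), 4 h was 1.95-fold above 2 h (1.93 to 1.96), and 4 h was 2.40-fold above 0 h (2.37 to 2.42). In these single libraries, the median bin and the enriched regions changed differently over the 2 intervals of time. This is the lower contrast of the 0 h track, which could not be told apart from a flat background in that library. Fragments were shorter at 2 h, so folds per fragment are given beside those of calibrated depth. From 0 to 2 h the median bin went from a calibrated depth of 113 to 104, which is 0.923-fold and 1.08-fold per fragment, while the median enriched region was 1.48-fold higher and 1.74-fold per fragment. From 2 to 4 h the median bin was 2.24-fold higher and 1.96-fold per fragment, close to the 2.13-fold and 1.87-fold of the median region. Most regions were chosen at 2 or 4 h, which favours higher values than at 0 h. In the 1513 regions of 0 h, whose choice favours lower values later, the median region was 1.41-fold higher at 2 h than at 0 h, or 1.66-fold per fragment, and 2.03-fold higher at 4 h than at 2 h, or 1.78-fold per fragment. S. cerevisiae reads alone gave 0.563-fold for 2 h over 0 h and 1.27-fold for 4 h over 0 h. These quotients were not scaled to library size, and the IP libraries held 6187114 reads in total at 2 h and 10571808 at 0 h. They partly follow sequencing depth and do not test the occupancy folds.

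**Figure D1:**
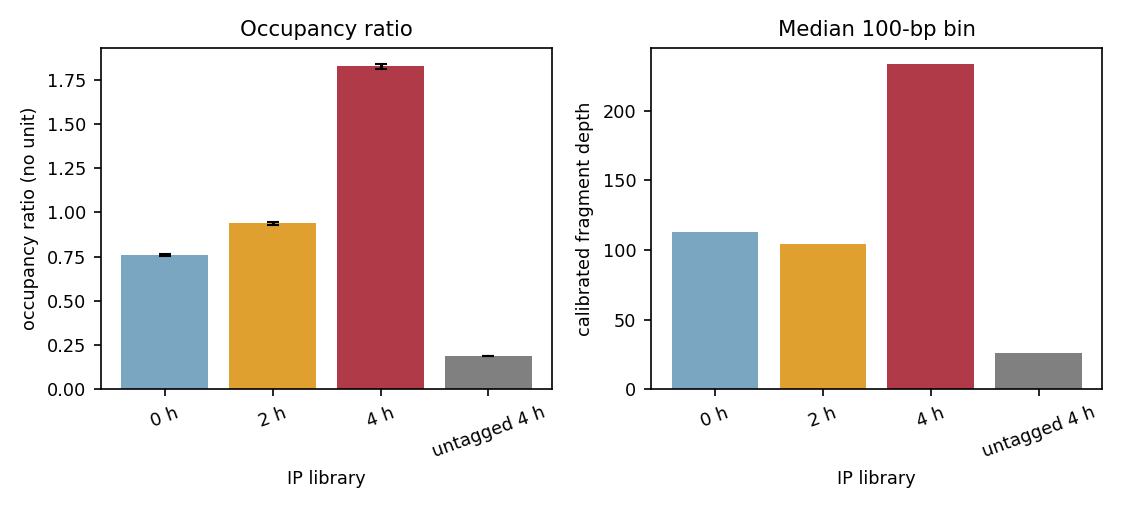
Occupancy ratio (left, bars with 95% counting intervals) and calibrated fragment depth of the median 100 bp bin (right) for the 3 tagged IP libraries and the untagged one. The tagged 4 h bars, 1.83 and 233, are the highest, and the untagged ones, 0.189 and 26.3, the lowest. Calibrated depth is not corrected for fragment length.

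The third comparison asks where Top2 signal was concentrated and whether this differed between times. By the same rule, 1513 enriched regions were found at 0 h, 3111 at 2 h and 3022 at 4 h. Regions were narrow, with a median length of 300 bp at each time, and 84, 195 and 223 of them in time order reached 1 kb. At 0 h they covered 5.16% of the nuclear bins and held 14.7% of the signal. At 2 h these shares were 11.0% and 33.4%, and at 4 h 11.5% and 32.2%. The top 5% of bins held 15.0% of the signal at 0 h, 21.4% at 2 h and 19.4% at 4 h, where a flat track would give 5%. In the untagged track the same share was 15.3%, of which a few very high bins made much: it was 9.0% without bins of extreme untagged signal. The number of regions depends on the threshold: at 3 in place of 2, the numbers were 563, 1650 and 1467.

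Around the summits of 2928 regions of 4 h, mean relative signal was 2.81 at 0 h, 5.31 at 2 h, 4.85 at 4 h and 1.03 in the untagged track. Between 1.5 and 2 kb from the summit it was 1.23, 1.43, 1.42 and 1.07. The width midway between the flank and the summit was 296 bp at 0 h, 236 bp at 2 h and 270 bp at 4 h, and follows the order of the mean fragment lengths, 220, 188 and 214 bp. In calibrated depth the summits stood at 318, 553 and 1131 in time order, against 27.0 in the untagged track.

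**Figure D2:**
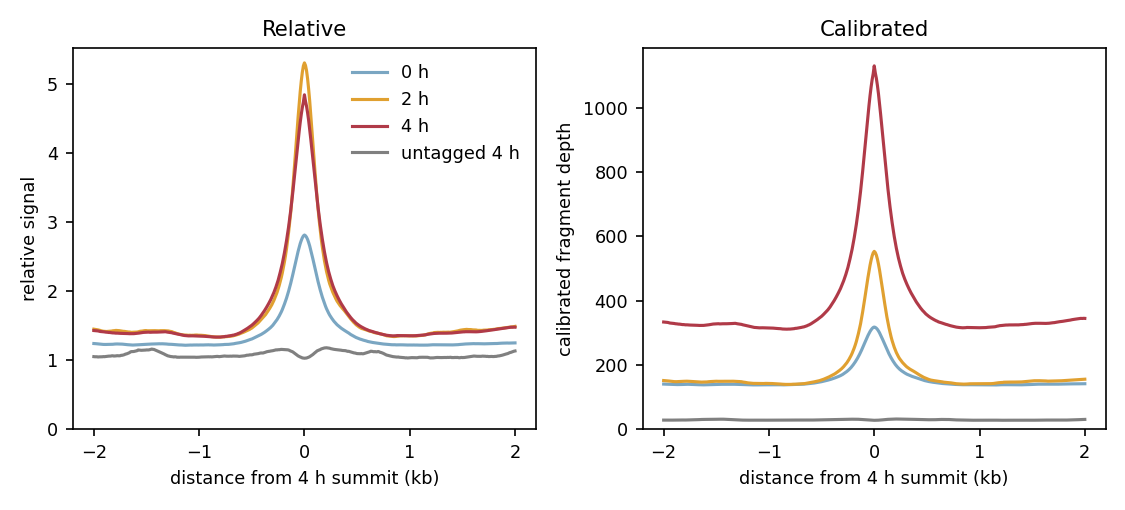
Mean relative signal (left) and calibrated fragment depth (right) against the distance in kb from the summits of 2928 regions enriched at 4 h, 1 line per IP library. Relative signal at the summit was 2.81, 5.31 and 4.85 at 0, 2 and 4 h and 1.03 untagged. Calibrated depth at the summit was 1131 at 4 h, above all other libraries. Summits were placed on the 4 h track itself.

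The 10 regions named for 4 h stood highest over the untagged track, by the naming rule. The region on chromosome 5 between 354701 and 356100 had a relative signal of 5.85 in the tagged and 0.641 in the untagged track, a quotient of 9.14 (counting interval 7.57 to 11.2). On chromosome 1, the region from 165901 to 166600 had a quotient of 9.11 (7.31 to 11.5), with 8.58 at 4 h, 9.13 at 2 h and 2.17 at 0 h. The highest relative signal among the 10, of 10.3, was on chromosome 10 between 365901 and 366400, where calibrated depth was 622 at 0 h, 1062 at 2 h and 2401 at 4 h against 33.7 without the tag. The other 7 were at 255201 to 255700 and 319101 to 320300 on chromosome 9, 211101 to 212300 on chromosome 2, 333201 to 334700 on chromosome 11, 612901 to 613800 on chromosome 14, 273801 to 274600 on chromosome 8 and 113701 to 114900 on chromosome 16. Their quotients lay between 7.65 and 8.91. Of the 10 regions, only that on chromosome 5 had a lower relative signal at 4 h than at 0 h, with 5.85 against 6.58. Chosen as the highest of 2928, these quotients tend to be overstated.

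**Figure D3:**
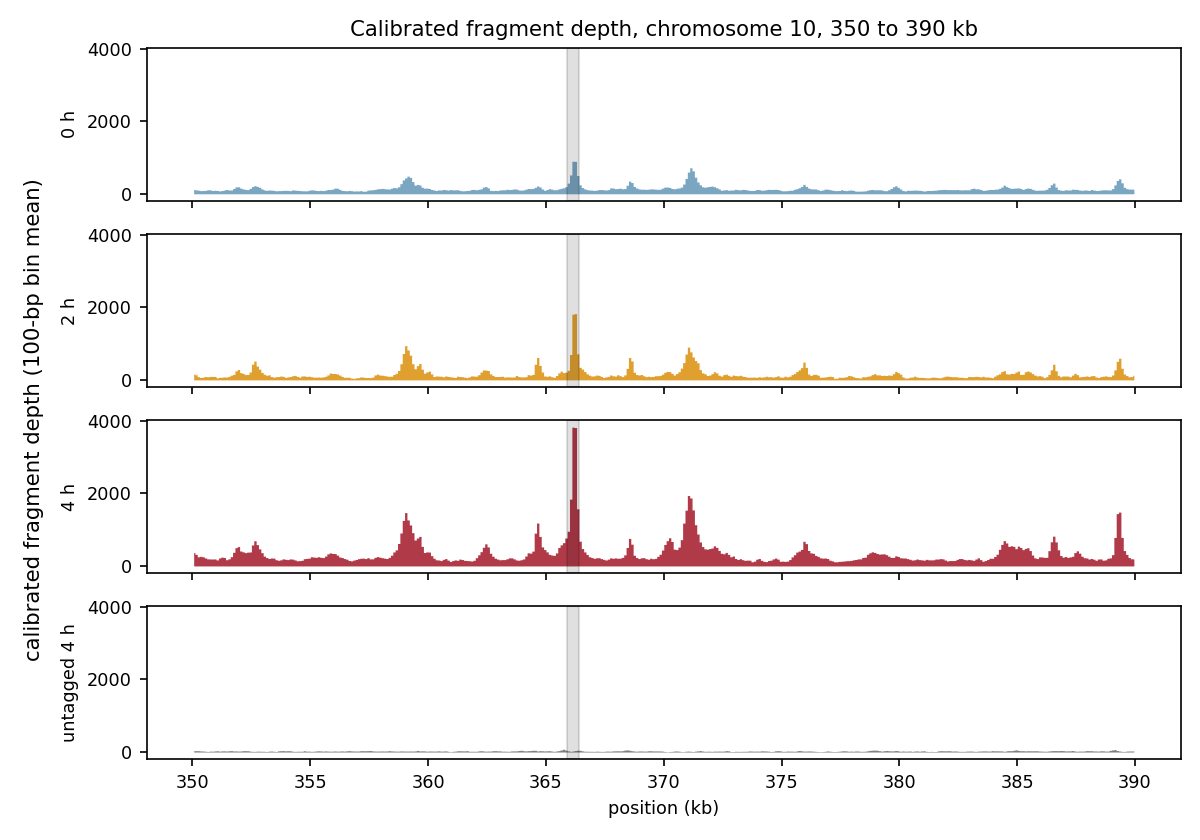
Calibrated fragment depth in 100 bp bins along chromosome 10 from 350 to 390 kb of ASM205788v1 in the 4 IP libraries, on a common vertical axis. The grey band marks the region from 365901 to 366400, with mean calibrated depths of 622, 1062 and 2401 at 0, 2 and 4 h and 33.7 untagged.

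The union of regions of the 3 times held 3462 regions, and their signal was compared between times. Relative signal at 2 h over 0 h had a median log2 ratio of 0.68, a fold of 1.60, with 3314 regions higher and 148 lower. From 2 to 4 h the median was -0.07, with 1407 higher and 2055 lower. At 4 h over 0 h it was 0.62 (quartiles 0.38 and 0.84), a fold of 1.53, with 3227 regions higher and 235 lower. By at least 2-fold, 434 were higher and 22 lower. Most regions of the union were chosen at 2 or 4 h, which favours higher values there: in the 1513 regions of 0 h, the median fold was 1.38, with 1262 higher and 251 lower. Calibration adds -0.12, 1.16 and 1.05 to these log2 ratios in the same order. Per fragment the added values are 0.12, 0.97 and 1.09, so the direction of the first depends on fragment length. In calibrated depth the median folds were then 1.48, 2.13 and 3.17, and per fragment 1.74, 1.87 and 3.26. Calibration turns the 2 to 4 h direction, with 3451 regions higher and 11 lower, and gives 3441 higher and 21 lower for 4 h over 0 h.

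**Figure D4:**
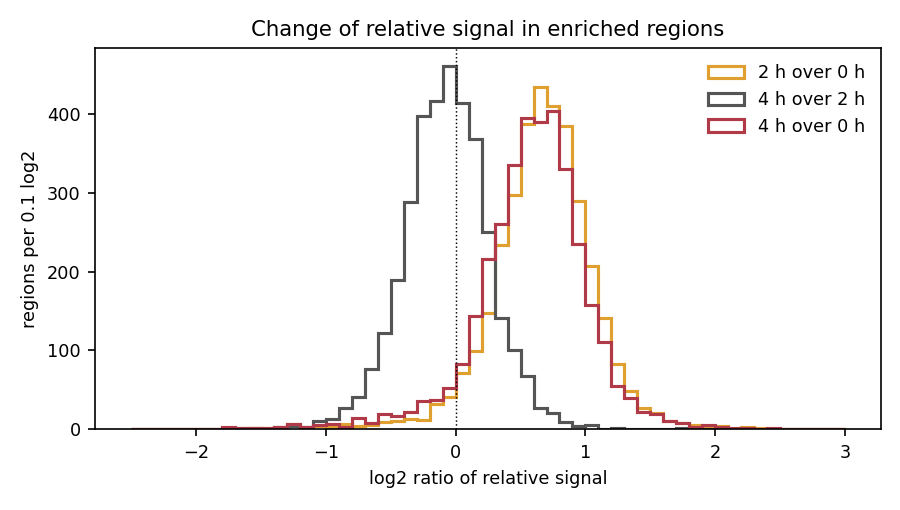
Number of regions by log2 ratio of relative signal, in steps of 0.1, for 3 pairs of times over the 3462 regions of the union. The medians were 0.68 for 2 h over 0 h, 0.62 for 4 h over 0 h and -0.07 for 4 h over 2 h, and the dotted line marks no change.

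Of the 3355 union regions away from chromosome ends and with untagged signal of at most 3, 1283 were higher at each step and 69 lower at each step in relative signal. The largest such rise was on chromosome 4 between 173801 and 174100, from 0.605 at 0 h to 2.82 at 4 h, 4.64-fold (counting interval 3.67 to 5.92). Next were 204101 to 204500 on chromosome 6 at 4.14-fold, 93501 to 94500 on chromosome 15 at 3.97-fold, 422301 to 423000 on chromosome 12 at 3.89-fold and 301601 to 302300 on chromosome 4 at 3.70-fold. The largest fall was on chromosome 16 between 346001 and 346800, from 5.34 at 0 h to 2.23 at 2 h and 1.58 at 4 h, 3.38-fold lower. In the other 4, relative signal was 3.29-fold lower at 305101 to 305900 on chromosome 5, 3.04-fold at 986901 to 987300 on chromosome 7, 2.74-fold at 52101 to 52600 on chromosome 4 and 2.62-fold at 68001 to 68700 on chromosome 15. These 5 regions were also lower at 4 h than at 0 h in calibrated depth, for example 369 against 603 on chromosome 16, although their lowest calibrated depth was at 2 h. Chosen as the largest of 1283 rises and 69 falls, the named folds tend to be overstated. The largest rise started from 85 fragments at 0 h, with a relative signal below the untagged 0.724.

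Sites of 0 h were mostly found again later. Of the bases enriched at 0 h, 90.0% were also enriched at 4 h, and of those enriched at 4 h, 40.5% were enriched at 0 h. Independent placement would give 5.20% for the latter, and the highest of 1000 circular shifts gave 8.26%. The 0 h list is shorter, so that at most 45.0% could be shared. Between 2 and 4 h, with lists of similar length, 81.5% of the 4 h bases were enriched at 2 h and 85.1% of the 2 h bases at 4 h, where independent placement would give 11.1% for the former. Both lists of each pair rest on the same untagged track, so part of the excess may come from it.

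Across 12008 bins of 1 kb, log2 relative signal had a Pearson correlation of 0.96 between 2 and 4 h, 0.92 between 0 and 2 h and 0.90 between 0 and 4 h. Spearman correlations were 0.94, 0.87 and 0.85. With the untagged track the tagged ones had Pearson correlations of 0.68 at 0 h, 0.58 at 2 h and 0.59 at 4 h and Spearman correlations of 0.41, 0.37 and 0.41.

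Regions near chromosome ends and differences between chromosomes were examined last. Within 20 kb of the ends there were 3.42 regions of 0 h per 100 kb, 13.9 of 2 h and 16.1 of 4 h. Beyond 200 kb from the ends the densities were 14.8, 28.2 and 27.2. The median bin near the ends, tagged over untagged and against the remaining bins, was 0.972 at 0 h, 0.936 at 2 h and 0.957 at 4 h. With a limit of 10 kb these values were above 1, from 1.05 to 1.08. Tracks were low near ends in all libraries, at a median of 0.700 for the untagged track within 20 kb. The rule for regions uses the median of the whole track, so the low density near ends may partly follow from this lower level.

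Mean relative signal was higher on longer chromosomes at 2 and 4 h, and the untagged track had the same trend once its highest bins were left out. At 4 h the tagged mean ranged from 1.28 on chromosome 3 to 1.45 on chromosome 5. Pearson's r with chromosome length was 0.65 at 4 h (permutation p = 0.00684, adjusted 0.0192), 0.63 at 2 h (p = 0.00959, adjusted 0.0192), 0.45 at 0 h (p = 0.0768, adjusted 0.102) and 0.12 in the untagged track (p = 0.666). The untagged value is set by a few very high bins. Without bins of untagged signal over 3, a setting chosen after seeing the data, r was 0.69 in the untagged track (permutation p = 0.00308, adjusted 0.0216 over 7 relations) and 0.65 at 4 h (p = 0.00666, adjusted 0.0233). Divided by the untagged mean of the same bins, r was 0.34 at 4 h (permutation p = 0.200), 0.16 at 2 h (p = 0.552) and -0.082 at 0 h (p = 0.762), so no relation particular to the tagged tracks was detected. Spearman's rho was 0.59 at 4 h (permutation p = 0.0172, adjusted 0.0343), 0.66 at 2 h (p = 0.00700, adjusted 0.0280), 0.43 at 0 h (p = 0.0989) and 0.45 untagged (p = 0.0833). Without chromosomes 4 and 1, the farthest from the median length, r was 0.59 at 4 h and 0.62 at 2 h. The tagged relation was weaker without the 20 kb ends, with r = 0.47 at 4 h (permutation p = 0.0651) and 0.39 at 2 h (p = 0.131). With the chromosome's median bin in place of its mean, r was 0.20 and -0.14.

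The highest untagged bins, named as background, all lay on chromosome 2 between 25501 and 25800. The highest had an untagged relative signal of 2360, and 2.62, 4.15 and 4.00 in the tagged tracks in time order. Altogether 31 peaks of at least 5 times the untagged median were at least 3 times as high there as in any tagged track, and they held 6.13% of the untagged library's aligned fragments. At 10 of them the 4 h track was also at 2 or more.

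**Figure D5:**
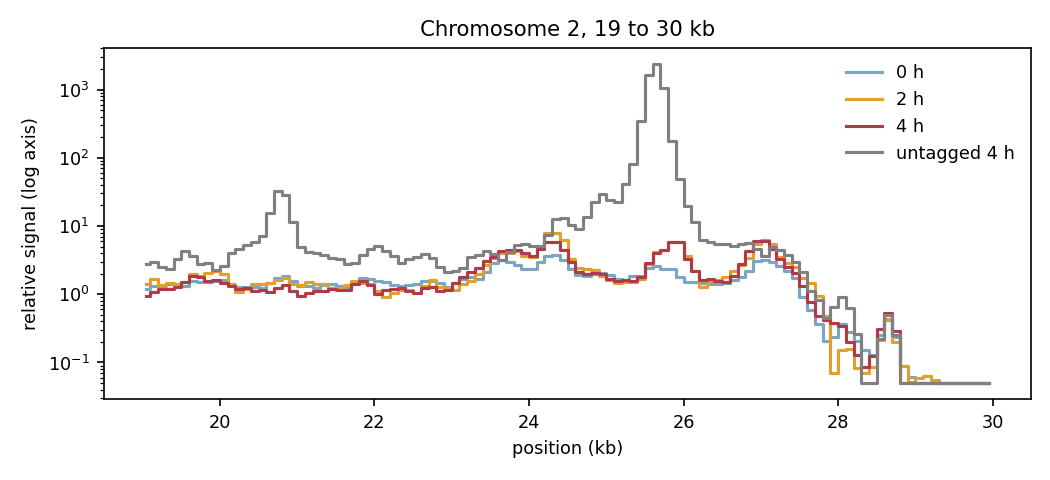
Relative signal in 100 bp bins on chromosome 2 from 19 to 30 kb, on a log axis, for the 4 IP libraries. The untagged track has a peak of 2360 near 25.6 kb, where the tagged tracks stand at 2.62, 4.15 and 4.00 in time order. Low values are drawn at the bottom of the axis.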

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

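The signal on sequence 17, taken to be mitochondrial DNA and left out of the comparisons of tracks, was above the untagged control at 0 h. Its median depth was 5.94 times the nuclear median there and 3.23 times in the untagged library. At 2 and 4 h it was 1.04 and 0.757 times the nuclear median. In calibrated depth these were 670 at 0 h, 108 at 2 h, 177 at 4 h and 84.9 untagged, not corrected for fragment length, and the share of the summed depth was 4.07%, 0.857%, 0.450% and 2.40%. Its reads are part of the occupancy ratios. No explanation for its level was tested.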

How the results depend on the processing

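Of 87 alternative values, 70 fixed in advance and 17 chosen after seeing the data, 26 stayed within the range of the reported one, 47 moved beyond it, 7 reversed, 5 lost their threshold and 2 gained it. Where values moved, the cause was not tested. Without replicates, the range is the counting interval for folds and shares, 1.5 times for counts of regions and the printed digits for correlations and medians. The settings fixed in advance for signal by gene part and for promoter signal were not run, for want of an annotation of this assembly. Simulated regions of 2-fold, which lie at the caller's own threshold, were mostly missed at each depth. The caller found 10 of 47 at the 0 h depth, 10 of 50 at the 2 h depth and 14 of 49 at the 4 h depth. Those of 3-fold were mostly found, with 44 of 46 at the 0 h depth. The depth of the untagged and WCE libraries was not varied.

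Without the WCE, occupancy was 10.9-fold for tagged over untagged at 4 h, 1.31-fold for 2 h over 0 h and 3.22-fold for 4 h over 0 h. By reads alone, without calibration or scaling to library size, the folds were 5.33, 0.563 (reversed) and 1.27, and so partly follow sequencing depth. With IP reads on sequence 17 left out, added after seeing the data, and without the excess of the 31 peaks in the untagged library, they were 10.5, 1.27 and 2.49, with the WCE reads as before. The authors' factors gave the same folds.

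The share of signal in the top 5% of bins at 0, 2 and 4 h and untagged was 12.6%, 16.1%, 15.3% and 13.9% in 1 kb bins, 14.7%, 21.0%, 19.1% and 9.0% without bins of high or low untagged signal, and 14.9%, 21.3%, 19.3% and 15.0% without chromosome ends. Correlations of 0 with 2 h, 0 with 4 h, 2 with 4 h and 4 h with untagged were 0.88, 0.87, 0.93 and 0.48 in 100 bp bins and 0.89, 0.87, 0.95 and 0.37 without bins of extreme untagged signal. Divided by the untagged track they were 0.87, 0.84 and 0.95. These last values say little, since flat simulated tagged tracks over the same untagged track gave 0.98, 0.99 and 0.98. The covariances were 0.27, 0.25 and 0.39 against simulated 0.22, 0.22 and 0.23.

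The 0 h count of 1513 regions became 2812 with thresholds of 1.5, 563 with thresholds of 3 and 2564 by calibrated difference. With thresholds of 3, the 3111 regions of 2 h became 1650 and the 3022 of 4 h became 1467. Their other counts stayed within 1.5 times, but the 4392 regions of 4 h by calibrated difference covered 63.9% of the bins, so that count does not describe separate sites. Added after seeing the data were counts with no comparison with the untagged track, 2031, 3676 and 3638 at 0, 2 and 4 h, and counts after thinning to the 2 h depth, 1479 at 0 h and 2970 at 4 h. Under each alternative run at all 3 times, 0 h had the fewest regions. The share of 4 h bases enriched at 0 h was 49.95% with thresholds of 1.5 and 30.8% with thresholds of 3. With thresholds of 1.5 the lists covered 11.4% of the bins at 0 h and 20.1% at 4 h. With thresholds of 3 they covered 1.61% and 4.74%. The highest share possible thus also fell, so the lower share does not show less overlap among stronger regions.

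The median log2 ratio of region signal, 4 h over 0 h, was 1.66 calibrated, 1.70 calibrated per fragment (added after seeing the data), 0.46 in regions of 0 h, 0.68 in those of 4 h, 0.61 in those of 2 h (added) and 1.06 with the untagged signal subtracted. Near chromosome ends, the quotient at 0, 2 and 4 h reversed to 1.07, 1.05 and 1.08 at 10 kb and was 0.929, 0.927 and 0.939 at 40 kb. The correlation with chromosome length lost its threshold without ends, with r = 0.39 at 2 h and 0.47 at 4 h. By medians it was 0.20 at 4 h, reversed to -0.093 at 0 h and -0.14 at 2 h, and was 0.62 in the untagged track, above the threshold. Without high untagged bins, added after seeing the data, the untagged r was 0.69, and the tagged r at 0, 2 and 4 h kept its side of the threshold. Over the untagged track, also added, r was -0.082, 0.16 and 0.34.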

Other observations

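Among the tests of explanations, those on fragment length, flat background, input correction, single immunoprecipitations and the untagged peaks were chosen after the result was seen. Earlier tests of a flat background on regions lower at 4 h were dropped, since those regions do not show the pattern. Regions of 4 h were spread along the chromosomes rather than gathered in a few places. The gap between neighbouring summits had a median of 2.91 kb, just above the 2.65 to 2.86 kb of 100 random sets, and the longest was 27.4 kb. The random points had no minimum distance, while enriched bins close together were joined into 1 region. The small difference from the random sets therefore cannot be read as a spacing of the sites. In 5 groups of regions ordered by their 2 h signal, the median log2 ratio of 4 h over 0 h lay between 0.59 and 0.65. Regions weak at 2 h could enter the union through their 4 h signal, which favours a higher ratio in the weakest group. Its 4 h median of 2.34 was above its 2 h median of 2.11, and in the other groups the 4 h median was the lower. These values thus do not show whether weak and strong regions changed alike. Depth in bins 2 kb apart had a correlation of 0.12 at 0 h, 0.05 at 2 h, 0.04 at 4 h and 0.05 in the untagged track. On the 17 sequences, 105 kb had no depth in any track, of which the longest stretch, of 17.4 kb, was on chromosome 12 from 444341 to 461697.

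The first pattern is the lower contrast at 0 h, with 1513 regions against 3111 and 3022. Thinning the 0 h library to the 2 h depth left 1479 regions, but thinning a deeper library could hardly raise its count. The tracks as sequenced argue against depth, with a median bin of 103 at 0 h, 43 at 2 h and 112 at 4 h. Fragment length is argued against by 4 h, whose mean fragment of 214 bp is close to the 220 bp of 0 h. The 4 h track had 2.00 times as many regions as the 0 h track. A flat background at 0 h would leave all regions the same share of their 4 h excess over the median bin. That share was 0.492 in the median region of 2 h (quartiles 0.357 and 0.657), and a flat background cannot be told apart from a change in binding, because the scatter between replicate libraries is unknown. A change in where Top2 binds as cells enter meiosis is the biological hypothesis and stays open.

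The second pattern is the 2.40-fold higher occupancy at 4 h than at 0 h. Without reads on sequence 17 in the IP it was 2.49-fold, and without the WCE reads 3.22-fold, so neither accounts for it. Both changes could only raise the fold, given the larger share of sequence 17 at 0 h and the higher WCE quotient at 4 h. They are therefore no separate support for the rise. The share of sequence 17 in the WCE was not analysed here. Variation between single immunoprecipitations cannot be told apart from a change over time, because there was 1 library per time. More Top2 bound relative to the S. cerevisiae chromatin at 4 h may be the reason, as an untested hypothesis.

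The third pattern is the set of 31 peaks at least 3 times as high in the untagged track as in any tagged one, 10 of which also had a relative signal of at least 2 at 4 h. If the antibody bound these sites without a tag in all libraries, the calibrated depth at 4 h should be at least that of the untagged library. Per fragment it was lower by more than 2.40-fold, the largest fold of occupancy between tagged libraries, at 3 peaks. It was 14.1-fold lower on chromosome 2 from 24501 to 26600 and 6.99-fold on chromosome 7 from 209601 to 210200. All 31 peaks were chosen as higher in the untagged track, which favours such differences. If both IPs recovered binding without a tag equally well, which was not tested, the values argue against it at these 2 peaks on chromosomes 2 and 7. The third, at the end of chromosome 9 from 301 to 3900, was 2.78-fold lower. That is close to the 2.40-fold and under the 3.22-fold of 4 h over 0 h without the WCE, so it decides little there. By counting error alone, which leaves out variation between libraries, 7 were lower, and 14 with each library's median bin subtracted, the test first tried, while without the correction for fragment length 6 had a lower value at 4 h. For the peak on chromosome 9 and the other 28 peaks, antibody binding without a tag stays open. Foreign DNA or another tagged protein in that culture or library also stays open, since there was 1 untagged IP library to compare. No biological explanation was tested.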
